A study of Mus musculus with 16 samples.

How the data were processed

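RNA from the hippocampus of mice aged 9 months was measured by sequencing of polyadenylated transcripts in 16 libraries, 4 from each of wild-type (WT), Dp16, 5xFAD and 5xFAD-Dp16 animals, each group with 2 females and 2 males per the labels. Dp16 mice carry a duplication of the part of mouse chromosome 16 that corresponds to most of human chromosome 21, so that its genes are present in 3 copies. 5xFAD mice carry human transgenes, APP among them, with familial Alzheimer mutations, driven by Thy1 promoter sequences. Libraries are named by their group and the number in their title; these numbers are unique to each library and pair nothing. No batch, litter or breeding information was given in the labels, and whether each library came from a separate animal was taken from the design text, which counts 4 mice per group.

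Per the labels, RNA was extracted with TRIzol, and strand-specific libraries were made with the Tecan/Nugen Universal Plus mRNA kit and read as 150 bp pairs on a NovaSeq 6000. The submitters' processing notes name bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5, HTSeq 0.6.1 and the mouse build GRCm38. The role of each tool, the strand setting and the handling of reads that map to several places were not stated. The authors provided a table of raw read counts per gene for 55385 genes, which sum to between 16922937 and 25308693 per library. The deposited RPKM values (reads scaled by gene length and library total) were checked to equal the count divided by the library's column total and by 1 length per gene. The counts were used for every test, and the RPKM values for 1 alternative. Gene positions were taken from the GENCODE M21 annotation of GRCm38, matched by gene identifier without its version, which placed 55144 of the 55385 genes and 17123 of the 17132 tested.

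Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as factor and a minimum count of 10, which left 17132 genes. Libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.9445 to 1.13. A quasi-likelihood model with robust dispersion estimates was fitted to all 16 libraries with the 4 groups and sex as terms. A gene was called when its adjusted p (Benjamini-Hochberg over all genes tested) was below 0.05. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and levels as TMM-scaled CPM (counts scaled to a common library size) with the standard deviation (SD) over the 4 libraries. The 8 comparisons were Dp16 with WT, 5xFAD with WT, 5xFAD-Dp16 with 5xFAD, 5xFAD-Dp16 with Dp16, 5xFAD-Dp16 with WT, the interaction of the Dp16 and 5xFAD genotypes, females with males, and the difference of the 5xFAD effect between the sexes. The triplicated segment was taken as the genes from Lipi to Zbtb21 on chromosome 16.

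In all, 35 gene lists were fixed before the data were examined, as were the comparisons, the tests, most alternatives and the rule for naming genes. The lists cover plaque-associated and homeostatic microglia, complement, interferon response, the interferon receptor cluster of the segment, antigen presentation, reactive astrocytes, lysosome, orthologs of Alzheimer risk genes, excitatory neurons, dentate gyrus granule cells, CA1 and CA3 pyramidal cells, inhibitory neurons, astrocytes, mature oligodendrocytes, oligodendrocyte precursors, endothelial cells, mural cells, meningeal fibroblasts, choroid plexus, ependymal cells, thalamus, striatum, blood cells, lymphocytes and neutrophils, immediate early genes, synaptic proteins, cholesterol biosynthesis, the unfolded protein response, heat shock, oxidative phosphorylation, chromosome 21 orthologs on mouse chromosomes 10 and 17, clustered protocadherins, p53 targets and proliferation. Genes of the segment were taken out of every list except that of the receptor cluster. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 35 lists within a comparison, and again with the correlation estimated from the data. A list score per library was the mean log2 CPM of its members, set to 0 at the WT mean, and groups were compared on scores by two-sided exact permutation tests over the 35 splits of 4 against 4 libraries. The smallest p these can give is 0.0286.

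Genes were named by this rule. In each of the first 4 comparisons these were the 6 called genes outside the segment with the largest rises and the 6 with the largest falls, among genes with a mean log2 CPM of 0 or more, no overlap between the libraries of the groups, and a symbol other than a predicted gene. To these were added up to 4 called members of each list past the preset test, or the 2 of smallest p where none was called. The Dp16 comparisons added the 6 segment genes of smallest p and App, Sod1, Dyrk1a, Rcan1, Ifnar1, Ifnar2, Ifngr2, Il10rb, Olig1 and Olig2. The genes added to the 5xFAD comparisons included App, Thy1, Apoe, Trem2, Cst7, Itgax, Gfap and C4b. In the other comparisons the 5 called genes of smallest p were named, or the 3 of smallest unadjusted p where none was called, and any list could give up to 4 members. A gene with 1 to 3 counts in a whole group is given as a ratio with its 95% counting interval. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

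The tests of genes, and with them the median of the segment, were tried again with the size factors of DESeq2, with TMM factors computed without the segment, with no filter and with a filter at a mean CPM of 1, with DESeq2 1.42.0, with limma-voom, with limma on the log2 of the RPKM plus 0.1 or plus 1, without sex as a term, with the compared groups alone, with the sample number of the source name as a block, within females and within males, and without each library in turn. The tests of lists were tried again with an estimated correlation, with the size factors of DESeq2 and without each library in turn only. After the data had been seen, the scores of thalamus and choroid plexus markers were added as covariates, the 6 libraries of high thalamus markers were left out, and a trend of expression on gene length was removed from each library, for genes and lists alike. The tests were tested on simulated data made from the real means and library sizes with 50 genes changed at each fold. For 5xFAD with WT, edgeR recovered 78% of genes raised 2-fold and 56% of those raised 1.5-fold, with 7 false calls. For Dp16 with WT it recovered 76% and 46%, with 9 false calls, and for the interaction 46% and 18%, with 7 false calls. The simulated genes varied independently of each other, without the differences in tissue content seen between the real libraries. These rates need not hold for the real data. Other splits of the same libraries were tested in the same way as the real groups. Figures were drawn in Python 3.11.15. All 16 libraries and columns were used.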

Results

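Gene expression was measured by sequencing of polyadenylated RNA in the hippocampus of 9-month-old mice of 4 genotypes, wild type (WT), Dp16, 5xFAD and 5xFAD-Dp16, with 4 libraries per genotype, 2 from females and 2 from males. Total gene counts were 16922937, 20060624, 21573963 and 24011935 in WT replicates 2, 4, 7 and 16, and 25308693, 19823038, 23332985 and 23209597 in Dp16 replicates 3, 5, 12 and 14. They were 23167997, 25290750, 20227287 and 25201983 in 5xFAD replicates 6, 10, 13 and 15, and 22926803, 22997103, 21392403 and 21764058 in 5xFAD-Dp16 replicates 1, 8, 9 and 11. Of 55385 genes in the table, 17132 were tested, and values below rest on 4 libraries per group. Mitochondrial transcripts took 4.96% to 6.87% of counts. Libraries also differed in markers of neighbouring brain tissue. Scores of the thalamus list were between 1.04 and 1.65 (log2) in 6 libraries, namely WT 4, Dp16 14, 5xFAD-Dp16 1 and 5xFAD 6, 13 and 15, and between -0.74 and -0.35 in the other 10. The 5xFAD group thus held 3 of the 6. The choroid plexus list scored 0 ± 1.56 (SD) in WT, -3.07 ± 1.21 in Dp16, -1.42 ± 2.39 in 5xFAD and -2.31 ± 1.87 in 5xFAD-Dp16.

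The comparison of Dp16 with WT asked what the duplication changed without amyloid transgenes. It was above all a rise of the genes carried in 3 copies. Of 39 genes called, 36 lay in the triplicated segment of chromosome 16 (GRCm38, 75540514 to 97962622), and all 36 rose. Over the 105 genes of the segment tested, of which 90 are protein coding, the median log2 fold change was 0.56, or 1.48-fold (quartiles 0.33 and 0.66). Values were positive for 92, and 67 rose when adjusted over the list alone. The 95% interval of the single gene held a 1.5-fold change for 85 genes, lay above it for 4 and below it for 16. App, the amyloid precursor gene (ENSMUSG00000022892.11, chromosome 16, 84949685 to 85173766), rose 1.59-fold (log2 0.67 ± 0.079 SE, adjusted p = 0.000856), from 2004 ± 39.4 to 3182 ± 89 CPM (SD). Cct8, a chaperonin subunit, rose 1.6-fold (0.67 ± 0.067, adjusted p = 0.000235), and Rcan1, an inhibitor of calcineurin, 1.61-fold (0.68 ± 0.076, adjusted p = 0.000723). Jam2, a junction protein, rose 1.7-fold and Gart, an enzyme of purine synthesis, 1.52-fold. The kinase gene Dyrk1a rose 1.42-fold (0.50 ± 0.075, adjusted p = 0.00393) and the superoxide dismutase gene Sod1 1.4-fold (0.48 ± 0.076, adjusted p = 0.00612). Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, had log2 values of 0.34 ± 0.09 and 0.30 ± 0.11 and were not called (adjusted p = 0.381 and 0.705). The mean log2 ratio of the segment per library was 0 ± 0.11 (SD) in WT, 0.44 ± 0.043 in Dp16, 0.11 ± 0.097 in 5xFAD and 0.58 ± 0.093 in 5xFAD-Dp16. For these means the exact two-sided permutation test gave p = 0.0286, the smallest possible, for Dp16 against WT and for 5xFAD-Dp16 against 5xFAD. Medians per library over segment genes with a mean log2 CPM of 3 or more did not show the same order. They were 0.56 to 0.57 in Dp16, 0.49 to 0.57 in 5xFAD-Dp16, -0.068 to 0.052 in 5xFAD and -0.027 to 0.028 in WT. The 412 tested genes of chromosome 16 outside the segment had a median of 0.014.

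**Figure D1:**
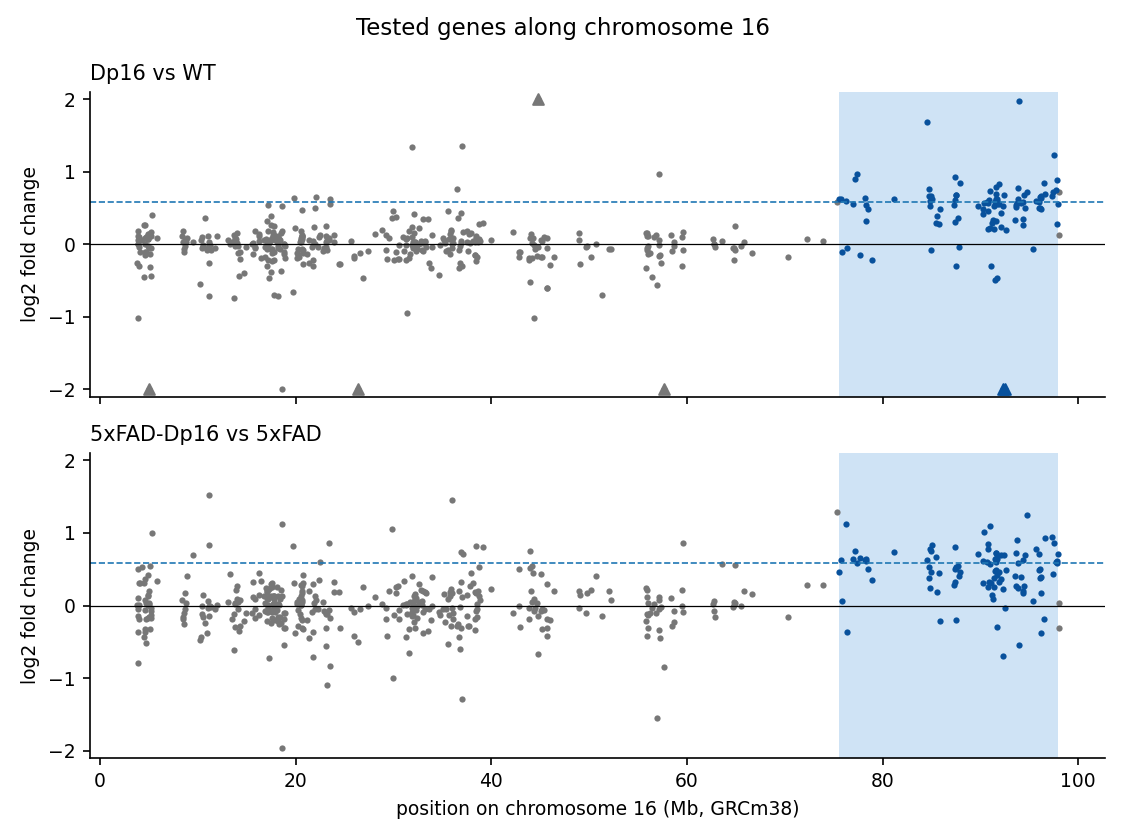
Log2 fold change of each tested gene (vertical axis) along chromosome 16 in Mb of GRCm38 (horizontal axis), Dp16 against WT in 1 panel and 5xFAD-Dp16 against 5xFAD in the other; blue points are the 105 genes of the shaded segment, triangles are values beyond the axis, and the dashed line is the log2 of 1.5-fold. The segment genes had medians of 0.56 and 0.51, against 0.014 and -0.0037 for the 412 genes outside it.

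The interferon receptor cluster of the segment rose in Dp16 (2 of 4 called, 3 when adjusted over the list alone, median 0.56, adjusted p = 0.00017 with an estimated correlation). Its called members were Ifngr2 (1.72-fold, 0.78 ± 0.11, adjusted p = 0.00221) and Ifnar1 (1.5-fold, 0.59 ± 0.067, adjusted p = 0.000778; ENSMUSG00000022967.13, chromosome 16, 91485238 to 91507441). Ifnar2 stood at 0.53 ± 0.1 (adjusted p = 0.0553) and Il10rb at 0.21 ± 0.17. Outside the segment 3 genes were called. The pigment gene agouti (a, ENSMUSG00000027596.10, chromosome 2, 154791402 to 155051012), which encodes a melanocortin receptor antagonist, had 163 counts in the 4 Dp16 libraries and 1 in the 4 WT libraries. This is a ratio of 150 (95% counting interval 26.6 to 5960, adjusted p = 0.000115). Slc5a5, the sodium-iodide symporter (ENSMUSG00000000792.2, chromosome 8, 70882889 to 70892757), rose 1.63-fold (0.71 ± 0.085, adjusted p = 0.000856). Cbs, cystathionine beta-synthase (ENSMUSG00000024039.15, chromosome 17, 31608894 to 31637238), fell from 30.6 ± 2.53 to 18 ± 2.21 CPM (-0.77 ± 0.096, adjusted p = 0.000985). Cbs is an ortholog of a human chromosome 21 gene that the duplication does not carry. It was the 1 gene to fall among the 37 such genes on chromosomes 10 and 17, whose median was 0.024 and mean -0.081. It was also the 1 gene called in the astrocyte list.

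Beyond the segment, 7 lists passed in Dp16 with the preset correlation alone. The interferon response had a median of 0.14, with 38 of 49 genes positive (adjusted p = 0.67 with an estimated correlation). Its Nmi and Zbp1 stood at -0.44 ± 0.14 and -1.50 ± 0.46. Its preset call was lost without WT 2 (median 0.099), WT 16 (0.12) or Dp16 12 (0.023). Homeostatic microglia had a median of -0.099 (adjusted p = 0.61 with an estimated correlation; Sall1, a microglial transcription factor, at -0.29). This call was lost without WT 16 (-0.035) or Dp16 14 (-0.12). Cholesterol biosynthesis had 21 of 23 genes positive (median 0.16, adjusted p = 0.14 with an estimated correlation), with Fdft1 at 0.30 (adjusted p = 0.566) and Hmgcs1 at 0.28 (adjusted p = 0.705). Synaptic proteins had a median of 0.11 (adjusted p = 0.78 with an estimated correlation; lost without WT 4 at 0.061 or Dp16 3 at 0.08). Heat shock genes had a median of 0.11 (adjusted p = 0.61 with an estimated correlation; lost without WT 16 at 0.073, Dp16 3 at 0.1 or Dp16 5 at 0.065). Meningeal fibroblasts had all 13 genes negative (median -0.56, adjusted p = 0.66 with an estimated correlation; lost without WT 7 at -0.046). Choroid plexus genes were all negative (15 of 15, median -3.41, adjusted p = 0.4 with an estimated correlation), among them Kcnj13 at -3.70 and Steap1 at -3.75. The choroid plexus scores differed by -3.07 with an exact permutation p of 0.0571. Without the 6 libraries of high thalamus markers 69 genes were called, 57 higher and 12 lower, with DESeq2 72 and without a low-count filter 360, of which 279 were lower.

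The comparison of 5xFAD with WT asked what the amyloid transgenes changed. In the main fit it gave the widest response of the series, with 909 genes higher and 335 lower, and the rise was led by microglia. Plaque-associated microglia genes rose (29 of 33, 32 when adjusted over the list alone, median 2.02, adjusted p = 0.00015 with an estimated correlation). Cst7, a cystatin induced in microglia at plaques (ENSMUSG00000068129.5, chromosome 2, 150570415 to 150578944), went from 0.239 ± 0.0805 to 85.8 ± 39.4 CPM (log2 8.46 ± 0.58, adjusted p = 9.54e-07). The integrin Itgax rose 66.5-fold (6.05 ± 0.39), the lectin receptor Clec7a 59-fold (5.88 ± 0.53). The protease Ctse rose 50.6-fold, the transglutaminase Tgm1 42.7-fold and the checkpoint receptor Pdcd1 30.5-fold. Trem2, a lipid-sensing receptor of microglia (ENSMUSG00000023992.14, chromosome 17, 48346401 to 48354147), rose 9.57-fold, from 10.2 ± 1.46 to 99.6 ± 30 CPM (3.26 ± 0.17, adjusted p = 1.26e-08). Its adaptor Tyrobp rose 7.09-fold, and the lysosomal protease gene Ctss 4.07-fold. Homeostatic microglia genes rose too (12 of 16, 12 when adjusted over the list alone, median 0.95, adjusted p = 0.0026 with an estimated correlation). Gpr34 stood at 1.51, Olfml3 at 1.39 and Cx3cr1 at 1.19.

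Complement genes rose in 5xFAD (10 of 15, 11 when adjusted over the list alone, median 1.37, adjusted p = 0.00015 with an estimated correlation). The initiator genes C1qa, C1qb and C1qc rose 4.89-fold, 4.32-fold and 4.37-fold and C4b 4.24-fold (2.08 ± 0.14, adjusted p = 2.02e-07), although C4a is a close paralog. Interferon response genes rose (42 of 49, 48 when adjusted over the list alone, median 1.31, adjusted p = 0.0011 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose 8.08-fold, Ifit3 3.7-fold, Irgm1 2.27-fold and Parp9 by 1.36 on the log2 scale. Antigen presentation genes rose (21 of 22, all 22 when adjusted over the list alone, median 1.58, adjusted p = 0.00061 with an estimated correlation). B2m, the light chain of class I molecules, rose 2.99-fold, H2-D1 3.14-fold and H2-K1 2.58-fold. Reactive astrocyte genes rose (15 of 27, 16 when adjusted over the list alone, median 0.88, adjusted p = 0.0026 with an estimated correlation). Gfap, the astrocyte filament (ENSMUSG00000020932.14, chromosome 11, 102887336 to 102900912), rose 4.38-fold, from 462 ± 9.27 to 2064 ± 577 CPM (2.13 ± 0.14, adjusted p = 1.98e-07). Cd14 rose 4.57-fold and Serpina3n 3.28-fold. Lysosome genes rose (18 of 34, 24 when adjusted over the list alone, median 0.37, adjusted p = 0.0026 with an estimated correlation). Gusb stood at 1.67, Hexa at 1.26, Grn at 1.16 and Ctsa at 0.85. Of 35 orthologs of Alzheimer risk genes 14 rose and 3 fell (17 and 4 when adjusted over the list alone, median 0.37, adjusted p = 0.0048 with an estimated correlation). The myeloid transcription factor Spi1 rose 2.81-fold and Ctsh stood at 1.57. The 3 that fell, named after their values were seen, were Slc24a4 (-0.62), the sorting receptor Sorl1 (-0.54) and Ank3 (-0.40). Apoe, the main lipid carrier of the brain (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188), rose 1.78-fold (0.84 ± 0.12, adjusted p = 0.000301).

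**Figure D2:**
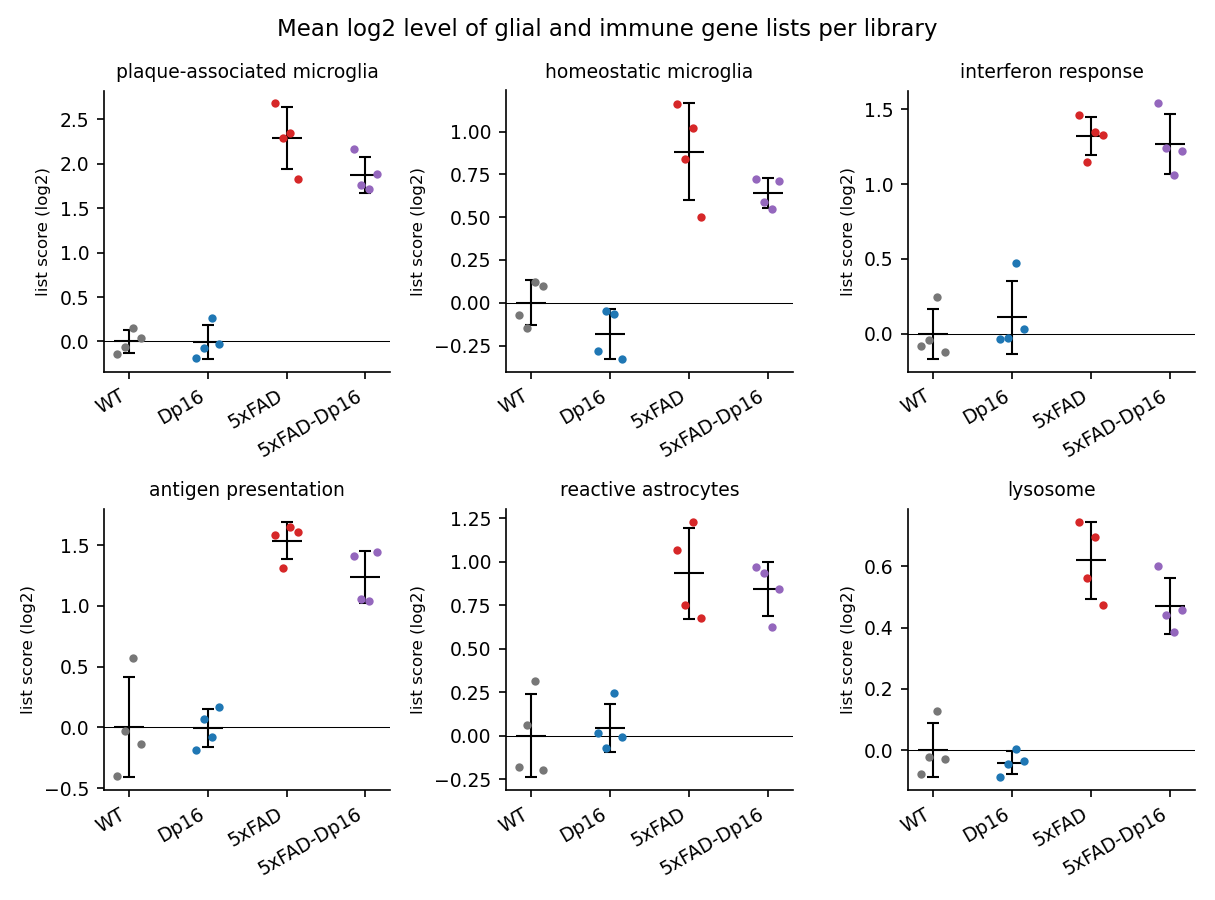
List scores per library (vertical axis, mean log2 CPM of the list's genes with the WT mean set to 0) for plaque-associated microglia, homeostatic microglia, interferon response, antigen presentation, reactive astrocytes and lysosome in the 4 genotypes; points are libraries and bars the mean and SD of 4. The plaque-associated score was 2.28 ± 0.35 in 5xFAD and 1.88 ± 0.2 in 5xFAD-Dp16, against 0 ± 0.13 in WT and -0.0048 ± 0.19 in Dp16.

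The 5xFAD transgenes are human sequences, and mouse App (-0.20 ± 0.079, adjusted p = 0.128) was not called. Thy1 counts, whose gene gave the transgenes their promoter (ENSMUSG00000032011.5, chromosome 9, 44043384 to 44048579), rose 2.68-fold, from 749 ± 39.9 to 2010 ± 607 CPM (1.42 ± 0.16, adjusted p = 2.12e-05).

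**Figure D3:**
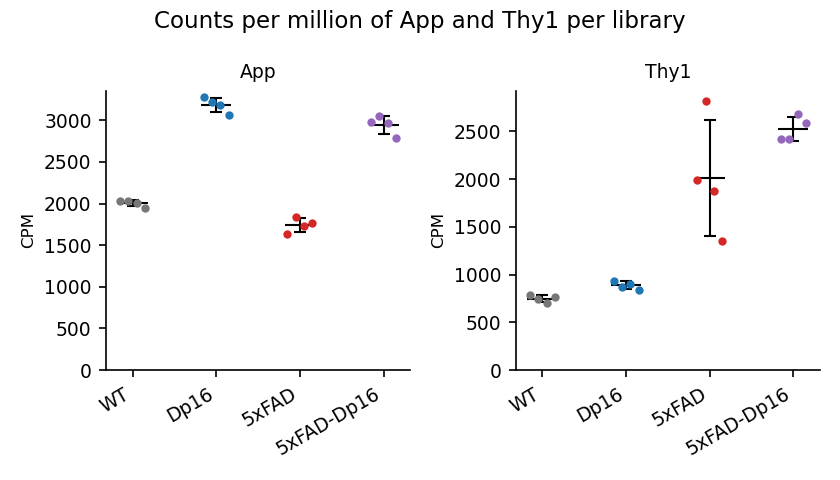
Expression of mouse App and Thy1 in CPM (vertical axis, from 0) per library in the 4 genotypes; points are libraries and bars the mean and SD of 4. App stood at 3182 ± 89 and 2946 ± 110 in the groups with the duplication and at 2004 ± 39.4 and 1744 ± 81.3 in the others, and Thy1 at 2010 ± 607 and 2525 ± 129 in the groups with the transgenes and at 749 ± 39.9 and 888 ± 40.7 in the others.

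Among the genes that fell in 5xFAD were neuronal ones, in lists that passed with the preset correlation alone. The 5xFAD group held 3 of the 6 libraries of high thalamus markers (scores 0.68 above WT, exact permutation p = 0.486). Excitatory neuron scores were -0.66, -0.37 and -1.34 in these libraries, 5xFAD 6, 13 and 15, and -0.072 in 5xFAD 10. The library of high thalamus markers also had the lowest such score of each other group (WT 4 -0.34, Dp16 14 -0.40, 5xFAD-Dp16 1 -0.34). For this list the transgenes and the tissue content thus cannot be told apart. Inhba, an activity-regulated activin subunit (ENSMUSG00000041324.14, chromosome 13, 16011851 to 16031621), fell from 6.98 ± 1.39 to 3.59 ± 0.392 CPM (-0.96 ± 0.19, adjusted p = 0.00462), and this call held without each single library. The other falls were Wnt2 (-1.21 ± 0.3), Gpr63 (-0.99 ± 0.28), the ephrin receptor Epha6 (-0.97 ± 0.23), Tmem200a (-0.89 ± 0.21) and the NMDA receptor subunit Grin2a (-0.87 ± 0.25, adjusted p = 0.0499). In this order they lost their calls in 5, 7, 4, 2 and 6 of 8 fits without 1 library. Excitatory neuron genes were negative in all 16 of the list (median -0.53, 3 fell, 5 when adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). The receptor subunits Gria2 (-0.54) and Grin1 (-0.41) fell, and lost their calls in 7 of 8 such fits. CA1 and CA3 pyramidal genes had a median of -0.62 (2 of 14 fell, 5 when adjusted over the list alone, adjusted p = 0.27 with an estimated correlation). Wfs1 and Man1a stood at -0.65 and lost their calls in 6 and 5 of these fits. Synaptic proteins had a median of -0.32 (2 of 30 fell, 5 when adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Nrxn3 stood at -0.45 and Pclo at -0.66, with calls lost in 3 and 6. Immediate early genes had a median of -0.48 (Fosb fell, -0.83 ± 0.19, adjusted p = 0.0151; 9 when adjusted over the list alone; adjusted p = 0.27 with an estimated correlation). Clustered protocadherins, close paralogs that give neurons their surface identity, had a median of -0.32 (5 of 57 fell, 8 when adjusted over the list alone, adjusted p = 0.27 with an estimated correlation). Pcdha12 and Pcdhga2 stood at -0.61, with calls lost in 3 and 6. Inhibitory neuron genes had a median of -0.22 (adjusted p = 0.27 with an estimated correlation; lost without 5xFAD 13 at -0.16), with Cnr1 at -0.64.

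Smaller shifts in other lists passed in 5xFAD with the preset correlation alone. Astrocyte genes had a median of 0.19 (4 of 15 rose, 5 when adjusted over the list alone, adjusted p = 0.27 with an estimated correlation). The water channel gene Aqp4 stood at 0.90 and Mlc1 at 0.45. Mature oligodendrocyte genes had a median of 0.49 over 17 genes, 4 of them called when adjusted over the list alone and 0 over all genes (adjusted p = 0.53 with an estimated correlation; lost without 5xFAD 15 at 0.23), with the transferrin gene Trf at 0.69. Without the 6 libraries of high thalamus markers the median turned to -0.34. Mural cells had a median of 0.42 over 12 genes (adjusted p = 0.43 with an estimated correlation), with Higd1b at 0.98. The mural call was lost without WT 2 (0.30), WT 4 (0.36), 5xFAD 10 (0.33) or 5xFAD 13 (0.35). Cholesterol biosynthesis had a median of 0.22 (2 of 23 rose, 2 when adjusted over the list alone, adjusted p = 0.27 with an estimated correlation; lost without 5xFAD 10 at 0.15). Stard4 stood at 0.44 and Acat2 at 0.41. Oxidative phosphorylation had a median of 0.15 (adjusted p = 0.64 with an estimated correlation; lost without 5xFAD 6 at 0.094, and turned to -0.013 without the 6 libraries of high thalamus markers), with Ndufs6 at 0.27. Lymphocyte and neutrophil genes had a median of 0.99 (2 of 8 rose, 3 when adjusted over the list alone, adjusted p = 0.27 with an estimated correlation). Cd3e, of the T cell receptor complex, had 52 counts in 5xFAD and 3 in WT, a ratio of 14.4 (95% counting interval 4.67 to 72.3), and Ighm, of B cells, stood at 0.87. Choroid plexus genes had a median of -0.75 (adjusted p = 0.68 with an estimated correlation), with Kl at -0.89. Their preset call was lost without WT 4 (-0.80), WT 7 (0.15), WT 16 (-0.74), 5xFAD 6 (-0.41) or 5xFAD 10 (-0.34).

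The remaining lists did not pass in 5xFAD. Their medians were -0.18 for dentate gyrus granule cells, 0.17 for endothelial cells, 0.49 for meningeal fibroblasts, -0.22 for ependymal cells, 0.65 for thalamus, 0.096 for striatum, 0.28 for blood cells and -0.11 for heat shock. Oligodendrocyte precursors had a median of 0.19, with C1ql1 up (0.52 ± 0.15), and the unfolded protein response a median of 0.032, with the stress factor Atf3 up (1.23 ± 0.34). Proliferation genes had a median of 0.10, with Top2a up (1.45 ± 0.36, adjusted p = 0.0222). For p53 targets the median was 0.033 and the mean 0.093, while camera gave the opposite sign with an adjusted p of 0.98, and Plk2 fell (-0.68 ± 0.2). The chromosome 21 orthologs on chromosomes 10 and 17 had a median of 0.05, with 4 of 37 up, among them the integrin Itgb2 (1.89 ± 0.12), S100b (0.87 ± 0.16) and Lrrc3 (0.89 ± 0.14). The receptor cluster had a median of 0.26, with Ifnar2 up (0.53 ± 0.1, adjusted p = 0.00595).

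**Figure D4:**
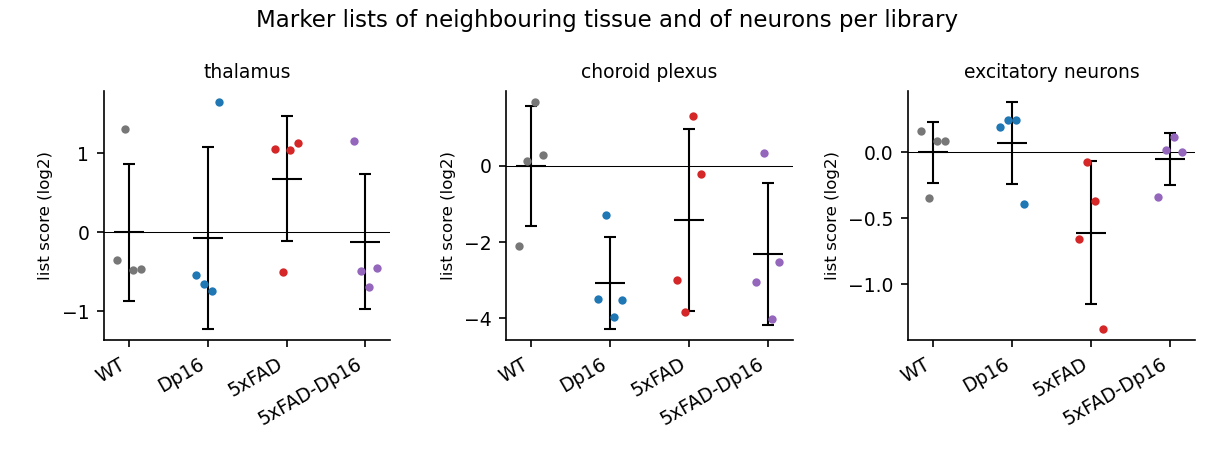
List scores per library (vertical axis, mean log2 CPM of the list's genes with the WT mean set to 0) for thalamus, choroid plexus and excitatory neurons in the 4 genotypes; points are libraries and bars the mean and SD of 4. Thalamus scores were above 1 in 3 of 4 5xFAD libraries and in 1 library of each other group, and excitatory neuron scores were -0.61 ± 0.54 in 5xFAD, 0 ± 0.23 in WT, 0.072 ± 0.31 in Dp16 and -0.052 ± 0.2 in 5xFAD-Dp16.

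The count of genes in 5xFAD rested on single libraries. It was 562 (34 lower) without WT 2, 712 (84 lower) without WT 7 and 641 (61 lower) without 5xFAD 6. It was 738 (70 lower) without 5xFAD 15 and 3486 (1864 lower) without 5xFAD 10, the only 5xFAD library of low thalamus score. The lower genes alone moved to 209 without WT 4, 185 without WT 16 and 533 without 5xFAD 13. Without the 6 libraries of high thalamus markers, which leaves 1 5xFAD library that is assumed to vary like the other groups, 283 genes were higher and 18 lower. DESeq2 called 2115 genes, and edgeR without a low-count filter 2692.

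The comparison of 5xFAD-Dp16 with 5xFAD asked what the duplication changed in the presence of the transgenes. Of 52 genes called, 32 lay in the segment and all 32 rose. The median of the segment was 0.51, or 1.42-fold (quartiles 0.32 and 0.67), with 96 of 105 genes positive and 67 up when adjusted over the list alone. App rose 1.69-fold, from 1744 ± 81.3 to 2946 ± 110 CPM (0.76 ± 0.079, adjusted p = 0.000181). Brwd1 rose 1.64-fold (0.72 ± 0.065, adjusted p = 5.99e-05), Zbtb21 1.64-fold, Dyrk1a 1.62-fold (0.70 ± 0.075, adjusted p = 0.000215) and Rcan1 1.63-fold. Not called were Sod1 (0.31, adjusted p = 0.0944), Olig1 (0.092, adjusted p = 0.589) and Olig2 (0.15, adjusted p = 0.448). The receptor cluster rose (2 of 4, 3 when adjusted over the list alone, median 0.51, adjusted p = 0.0091 with an estimated correlation). Its called members were Ifnar1 (1.56-fold, 0.64 ± 0.067) and Ifngr2 (1.65-fold, 0.72 ± 0.11), and Ifnar2 stood at 0.38 (adjusted p = 0.111) and Il10rb at 0.26 (adjusted p = 0.399).

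The genes called outside the segment in Dp16 against WT were called in the same direction here. Agouti (a) had 179 counts in the 5xFAD-Dp16 libraries and 3 in the 5xFAD libraries, a ratio of 66.8 (95% counting interval 22.5 to 327). Slc5a5 rose 1.52-fold (0.60 ± 0.085, adjusted p = 0.00202) and Cbs fell by 0.66 ± 0.095 (adjusted p = 0.00236). Over the 17027 tested genes outside the segment, fold changes by Dp16 on the WT and on the 5xFAD background correlated across genes with Pearson 0.263 and Spearman 0.259. Genes are not independent replicates. In all 10 genes outside the segment rose and 10 fell. With each library left out in turn, the genes called lower in this comparison numbered from 2 to 737. Plk5, a polo-like kinase of neurons and member of the dentate gyrus list (ENSMUSG00000035486.14, chromosome 10, 80356459 to 80365489), fell from 20.4 ± 3.34 to 9.42 ± 1.21 CPM (-1.12 ± 0.17, adjusted p = 0.0049). Tbx1, a transcription factor gene on chromosome 16 outside the segment (ENSMUSG00000009097.10, 18580979 to 18590671), fell from 1.73 ± 0.397 to 0.442 ± 0.116 CPM (-1.97 ± 0.39, adjusted p = 0.0452). It stood at -2.0 ± 0.4 in Dp16 against WT (adjusted p = 0.0508). Stxbp5l, of synaptic vesicle release (0.71 ± 0.13), the calcium-dependent kinase gene Camk4 (0.75 ± 0.15), Cdr1os (0.60 ± 0.12) and Pcdhb11 (0.85 ± 0.17) rose. AW047730 (-0.70), Ccdc107 (-0.51) and Fam50a (-0.50) fell. Tbx1 and each of these last 7 lost their calls in 5 to 7 of 8 fits without 1 library, and Plk5, Cbs, Slc5a5 and a in none.

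Several lists stood higher or lower in 5xFAD-Dp16 than in 5xFAD with the preset correlation alone, where 3 of the 4 5xFAD libraries were high in thalamus markers. Without the 6 libraries of high thalamus markers the medians turned to -0.0071 for synaptic proteins, -0.033 for inhibitory neurons, -0.12 for immediate early genes and 0.53 for mature oligodendrocytes, against the values below. Plaque-associated microglia genes were negative in all 33 (median -0.44, 7 lower when adjusted over the list alone and 0 over all genes, adjusted p = 0.36 with an estimated correlation). Tyrobp stood at -0.67 (adjusted p = 0.0997) and Cd9 at -0.48 (adjusted p = 0.107). Scores of the list differed by -0.41 (exact permutation p = 0.0857). Medians were -0.29 for homeostatic microglia (adjusted p = 0.41 with an estimated correlation), -0.26 for antigen presentation (0.48 for that p; H2-T23 at -0.56) and -0.17 for lysosome (0.39 for that p). Astrocyte genes had a median of -0.23, where Cbs fell (5 when adjusted over the list alone, adjusted p = 0.36 with an estimated correlation). Excitatory neuron genes were positive in all 16 (median 0.39, adjusted p = 0.39 with an estimated correlation). Synaptic proteins were positive in all 30 (median 0.32, adjusted p = 0.36 with an estimated correlation; Nrxn3 at 0.48 and Pclo at 0.76). CA1 and CA3 genes had a median of 0.40 (adjusted p = 0.36 with an estimated correlation; Wfs1 at 0.79) and inhibitory neurons 0.27 (adjusted p = 0.36 with an estimated correlation). Clustered protocadherins were positive in 47 of 57 (median 0.27, 1 rose, 5 when adjusted over the list alone, adjusted p = 0.36 with an estimated correlation). Oxidative phosphorylation genes were negative in 50 of 51 (median -0.28, 39 lower when adjusted over the list alone and 0 over all genes, adjusted p = 0.36 with an estimated correlation), with Ndufs3 at -0.34 (adjusted p = 0.0559). Further preset calls were dentate gyrus -0.14, mature oligodendrocytes -0.32, endothelial cells -0.16, meningeal fibroblasts -0.70, thalamus -0.60, immediate early genes 0.22 and cholesterol biosynthesis 0.14 (adjusted p = 0.48, 0.67, 0.39, 0.48, 0.62, 0.48 and 0.36 with an estimated correlation).

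Here too single libraries set the count, which was 89 without 5xFAD-Dp16 1, 32 without 5xFAD-Dp16 9 and 33 without 5xFAD 6. The count was 187 without 5xFAD 13 and 2045 without 5xFAD 10, which leaves only 5xFAD libraries of high thalamus markers. It was 101 (50 higher, 51 lower) without the 6 libraries of high thalamus markers, 36 of them in the segment, and 708 with DESeq2 and 1656 without a low-count filter. Preset calls of lists were lost for homeostatic microglia without 5xFAD 10 (-0.21) and dentate gyrus without 5xFAD-Dp16 1 (-0.047), 5xFAD 10 (-0.047) or 5xFAD 13 (-0.16). They were lost for inhibitory neurons without 5xFAD-Dp16 1 (0.37) or 5xFAD 13 (0.16), immediate early genes without 5xFAD-Dp16 1 (0.12) and endothelial cells without 5xFAD-Dp16 11 (-0.12) or 5xFAD 10 (-0.19). Those of mature oligodendrocytes were lost without 5xFAD-Dp16 1 (-0.32), 5xFAD-Dp16 9 (-0.22), 5xFAD 6 (-0.22) or 5xFAD 15 (0.0063), and those of thalamus without 5xFAD-Dp16 8 (-0.39), 9 (-0.32) or 11 (-0.44) or 5xFAD 6 (-0.44) or 13 (-0.39).

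The comparison of 5xFAD-Dp16 with Dp16 asked what the transgenes changed on the duplication. The microglial and astrocyte response was there again, with 512 genes higher and 6 lower, or 830 and 60 without a low-count filter. Plaque-associated microglia genes rose (24 of 33, 29 when adjusted over the list alone, median 1.65, adjusted p = 9.3e-05 with an estimated correlation). Cst7 rose 83.6-fold (6.39 ± 0.5, adjusted p = 5.39e-06), Itgax 34.5-fold, Clec7a 20.5-fold, Ctse 17.6-fold, the chemokine Ccl3 24.2-fold and Trem2 6.06-fold (2.60 ± 0.16). The metabolite receptor gene Hcar2 had 222 counts against 3, a ratio of 75 (95% counting interval 25.3 to 366). Homeostatic microglia genes rose (12 of 16, 13 when adjusted over the list alone, median 1, adjusted p = 0.00084 with an estimated correlation), with Cx3cr1 at 1.03. Complement genes rose (10 of 15, 11 when adjusted over the list alone, median 1.25, adjusted p = 7.7e-05 with an estimated correlation), C1qa 3.56-fold and C4b 3.78-fold. Interferon response genes rose (38 of 49, 46 when adjusted over the list alone, median 1.11, adjusted p = 0.00038 with an estimated correlation), with Zbp1 at 3.62. Antigen presentation genes rose (13 of 22, 21 when adjusted over the list alone, median 1.3, adjusted p = 0.00038 with an estimated correlation), B2m 2.71-fold. Reactive astrocyte genes rose (10 of 27, 15 when adjusted over the list alone, median 0.85, adjusted p = 0.0019 with an estimated correlation), Gfap 3.2-fold and Serpina3n 2.97-fold. Lysosome genes rose (14 of 34, 21 when adjusted over the list alone, median 0.32, adjusted p = 0.0019 with an estimated correlation), with Gusb at 1.17. Of the Alzheimer risk orthologs 14 of 35 rose (18 when adjusted over the list alone, median 0.42, adjusted p = 0.00038 with an estimated correlation), Apoe 1.51-fold (0.59 ± 0.12, adjusted p = 0.00792). Thy1 rose 2.84-fold (1.51 ± 0.16, adjusted p = 1.96e-05), while mouse App (-0.11, adjusted p = 0.67) was not called.

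Dusp4, a phosphatase of the MAP kinase pathway, fell in 5xFAD-Dp16 against Dp16 (-0.53 ± 0.13, adjusted p = 0.0331), as did Elmod1 (-0.36), Snx25 (-0.30), Usp39 (-0.27) and Ddx49 (-0.24), and these calls were lost in 6 or 7 of 8 fits without 1 library. Cd3e rose (2.43 ± 0.62, adjusted p = 0.0428; lost in 7 of 8 such fits), Top2a rose (1.74 ± 0.36) and Stard4 rose (0.53, adjusted p = 0.00223). Passing with the preset correlation alone were dentate gyrus genes at -0.26, lymphocytes and neutrophils at 0.55, synaptic proteins at -0.12, cholesterol biosynthesis at 0.17 (1 of 23 called, 4 when adjusted over the list alone), oxidative phosphorylation at -0.12, protocadherins at -0.092 and proliferation at 0.35 (adjusted p = 0.37, 0.24, 0.81, 0.19, 0.66, 0.74 and 0.096 with an estimated correlation). Those of lymphocytes were lost without Dp16 3 (0.53), Dp16 12 (0.52) or 5xFAD-Dp16 1 (0.36). Those of synaptic proteins were lost without Dp16 3 (-0.086), 5 (-0.09) or 12 (-0.095) or 5xFAD-Dp16 11 (-0.093). Those of protocadherins were lost without Dp16 3 (-0.051), 5 (-0.066) or 12 (-0.024) or 5xFAD-Dp16 1 (-0.035) or 11 (-0.066).

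The genes that rose with the transgenes overlapped between the backgrounds. Of the 909 genes higher in 5xFAD against WT and the 512 higher in 5xFAD-Dp16 against Dp16, 455 were shared, where 27.2 would be shared if the calls were independent, and no gene was called in opposite directions. Of the 335 lower in the first and the 6 lower in the second, 2 were shared (0.117 if independent). Of the 909, 881 had the same sign on the Dp16 background, with a median of 0.72 against 0.91. Of the 335, 301 had the same sign with a median of -0.12 against -0.41. These genes were chosen in the first comparison, and the 512 and 6 chosen in the second had medians of 1.17 and -0.33 there, against 1.25 and -0.16 in the first. Across all 17132 genes, which are not independent replicates, the fold changes correlated with Pearson 0.507 and Spearman 0.361.

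**Figure D5:**
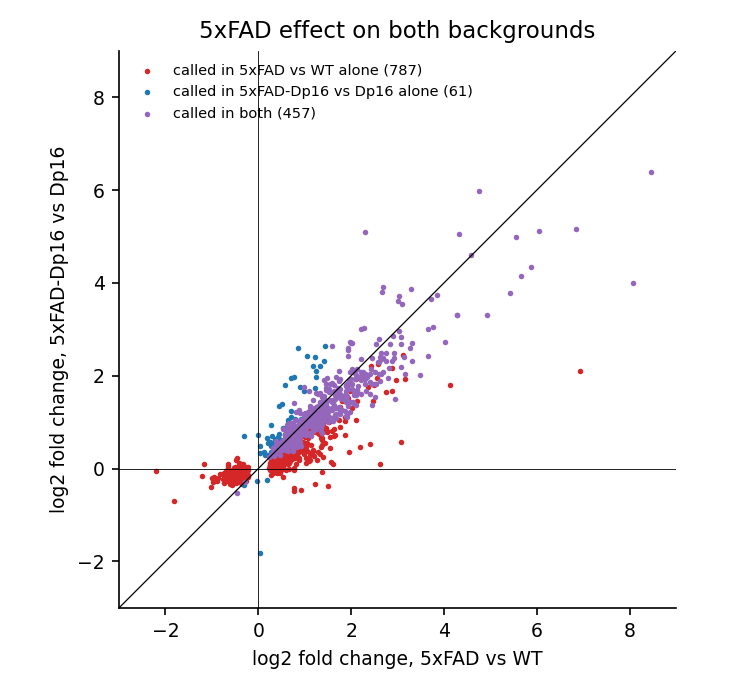
Log2 fold change of 5xFAD against WT (horizontal axis) and of 5xFAD-Dp16 against Dp16 (vertical axis) for each gene called in either; colours mark the 787 genes called in the first alone, the 61 called in the second alone and the 457 called in both, and the line marks equal change. Across these genes, which are not independent replicates, Pearson correlation was 0.893.

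The comparison of 5xFAD-Dp16 with WT asked what both changes did together. It called 531 genes higher and 17 lower, or 747 and 195 without a low-count filter, and 54 of the higher lay in the segment (median 0.56, 75 up when adjusted over the list alone). With each library left out in turn the lower genes numbered 7 to 20. The 4 receptor cluster genes all rose (4 when adjusted over the list alone, median 0.71, adjusted p = 0.00017 with an estimated correlation), with Ifnar2 at 0.91 ± 0.1 and Il10rb at 0.74 ± 0.17. Microglial genes led the rest. Mpeg1, a pore-forming protein of phagocytes, rose 4.76-fold (2.25 ± 0.11, adjusted p = 2.18e-08), Trem2 6.67-fold, C1qb 3.28-fold, C4b 5.44-fold and B2m 3.05-fold. Plaque-associated microglia genes rose (23 of 33, 27 when adjusted over the list alone, median 1.57, adjusted p = 6.3e-05 with an estimated correlation), as did homeostatic microglia (8 of 16, 12 when adjusted over the list alone, median 0.71, adjusted p = 0.0021 with an estimated correlation). Complement genes rose (8 of 15, 10 when adjusted over the list alone, median 1.12, adjusted p = 4.3e-05 with an estimated correlation), as did the interferon response (39 of 49, 47 when adjusted over the list alone, median 1.25, adjusted p = 0.00017 with an estimated correlation). Antigen presentation genes rose (14 of 22, 17 when adjusted over the list alone, median 1.15, adjusted p = 0.00017 with an estimated correlation). Reactive astrocyte genes rose (11 of 27, 14 when adjusted over the list alone, median 0.62, adjusted p = 0.001 with an estimated correlation), as did lysosome genes (13 of 34, 16 when adjusted over the list alone, median 0.25, adjusted p = 0.0025 with an estimated correlation). Alzheimer risk orthologs rose (12 of 35, 15 when adjusted over the list alone, median 0.19, adjusted p = 0.001 with an estimated correlation).

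Cholesterol biosynthesis rose in 5xFAD-Dp16 against WT, with all 23 genes positive and 7 called (15 when adjusted over the list alone, median 0.30, adjusted p = 0.0037 with an estimated correlation). Stard4, a sterol carrier, stood at 0.71 ± 0.092 (adjusted p = 0.000142), Fdft1, which makes squalene, at 0.53 (adjusted p = 0.00221) and Hmgcs1, which makes the precursor of mevalonate, at 0.51 (adjusted p = 0.00377). Cbs (-0.71 ± 0.096), Plk5 (-0.96 ± 0.17) and Tbx1 (-1.87 ± 0.39) fell. Passing with the preset correlation alone were dentate gyrus at -0.30, choroid plexus at -1.68, lymphocytes and neutrophils at 1.16, immediate early genes at -0.20 and oxidative phosphorylation at -0.11 (adjusted p = 0.1, 0.55, 0.054, 0.68 and 0.68 with an estimated correlation). That of immediate early genes was lost without WT 16 (-0.074) or 5xFAD-Dp16 8 (-0.18) or 11 (-0.21). Cd3e had 73 counts against 3, a ratio of 22.7 (95% counting interval 7.47 to 113).

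The interaction asked whether the duplication changed the response to the transgenes. No gene passed with edgeR (smallest adjusted p = 0.718, 1114 at an unadjusted p under 0.05), 1 passed with DESeq2 and none with limma-voom or limma on RPKM. Without the low-count filter edgeR called 290 genes, and on simulated interaction data DESeq2 made 37 false calls. The smallest p-values were those of the helicase gene Ddx49 (-0.42 ± 0.088), the primase subunit Prim1 (-1.21 ± 0.27) and Aldh1a7 (-4.16 ± 0.94). The segment had a median of 0.019. Of the lists, 14 passed with the preset correlation alone (adjusted p = 0.59 to 0.74 with an estimated correlation). Plaque-associated microglia had an interaction median of -0.33, antigen presentation -0.26, oxidative phosphorylation -0.28 and thalamus -0.76, and CA1 and CA3 genes 0.41, excitatory neurons 0.30 and protocadherins 0.27. Without the 6 libraries of high thalamus markers 15 genes were called, 3 of them higher and 12 lower, and the medians of excitatory neurons and thalamus turned to -0.045 and 0.16.

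Females and males differed at 11 genes, at 29 with DESeq2 and at 330 without a low-count filter. Xist, which silences 1 X chromosome in females, stood at 10.74, and the Y-linked Ddx3y at -12.92, Kdm5d at -11.36 and Uty at -10.86. Kdm6a, an X-linked demethylase that escapes silencing, rose 1.59-fold in females (0.67 ± 0.054). With the preset correlation alone 14 lists passed. Medians in females over males were 0.32 for complement, all 15 genes positive (8 when adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), and 0.24 for homeostatic microglia (5 when adjusted over the list alone, adjusted p = 0.21 with an estimated correlation). They were 0.24 for plaque-associated microglia (adjusted p = 0.32 with an estimated correlation), 0.24 for reactive astrocytes (0.22 for that p), 0.25 for antigen presentation (0.32 for that p), 0.17 for interferon response (0.32 for that p) and 0.12 for Alzheimer risk orthologs (0.21 for that p). The others were lysosome 0.078, meningeal fibroblasts 0.34, ependymal cells 0.34, blood cells -0.62, cholesterol biosynthesis -0.068, unfolded protein response 0.12 and oxidative phosphorylation -0.068 (adjusted p = 0.32, 0.62, 0.61, 0.44, 0.44, 0.32 and 0.61 with an estimated correlation). Preset calls were lost for meningeal fibroblasts without WT 7 (0.16), 5xFAD-Dp16 1 (0.12) or 9 (0.24) or 5xFAD 10 (0.30), and for ependymal cells without WT 7 (0.24), Dp16 14 (0.29), 5xFAD 10 (0.24) or 13 (0.29). They were lost for blood cells without WT 4 (-0.45) or 5xFAD-Dp16 8 (-0.28), and cholesterol biosynthesis without 5xFAD 10 (-0.022).

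The effect of the transgenes did not pass a test of difference between the sexes at any gene with edgeR (smallest adjusted p = 0.936, 639 at an unadjusted p under 0.05), DESeq2 or limma-voom, while edgeR without the low-count filter called 283 genes. Zfp972 (2.73 ± 0.61), Eif4ebp1, a regulator of translation (0.94 ± 0.22), and Vash2 (1.63 ± 0.39) had the smallest p-values. Of the lists 14 passed with the preset correlation alone, and none with an estimated correlation (adjusted p = 0.54 to 0.73). Plaque-associated microglia genes had a median difference of 0.28, female minus male, complement 0.30, excitatory neurons -0.41 and thalamus 2.11. High thalamus markers were uneven in this comparison. With the transgenes they were found in the females 5xFAD 6, 5xFAD 13 and 5xFAD-Dp16 1 and in the male 5xFAD 15. Without the transgenes they were found only in males, WT 4 and Dp16 14. Tissue content and a difference between the sexes thus cannot be fully told apart here. With thalamus and choroid plexus scores as covariates the medians were 0.26 for excitatory neurons, 0.11 for dentate gyrus, 0.12 for CA1 and CA3, 0.15 for synaptic proteins and 0.014 for thalamus.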

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

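The counts over other splits, and the tests below other than those of thalamus scores on the plaque-associated list and of genes near agouti, were chosen only after the result was seen.

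The 335 genes lower in 5xFAD against WT, with 6 lower in 5xFAD-Dp16 against Dp16, came from a comparison in which 3 of 4 5xFAD libraries scored high for thalamus. Of the 12 thalamus genes tested, 1 is also in another list and all are detected in the other libraries. In the 6 high libraries, which were picked by the mean of these genes, the most abundant stood at 103 CPM (Prkcd), 94.4 (Slc17a6) and 86.9 (Tcf7l2 and Calb2). In the other 10 libraries they stood at 26.9, 22.1, 8.52 and 39.3. Not all of the list went this way, as Ptpn3 stood at 69.2 against 70 and Lhx9 at 21.2 against 16.5. With thalamus and choroid plexus scores as covariates the median of the 335 genes was -0.35 (quartiles -0.44 and -0.29), against -0.41 (-0.51 and -0.34) in the main fit. With a trend on gene length removed (median 7177 bases in the lower genes, 3143 in all tested) it was -0.27 (-0.37 and -0.19). Whether thalamic tissue or gene length was the whole cause is not decided by these fits. The genes were chosen as low in the same libraries, which alone pulls their median below 0. A score of 12 genes may not take out all of a tissue's effect, and the corrections were not applied together. The corrections left 156 and 92 of the 335 calls. Of the 909 genes called higher in the same comparison they left 665 and 650. The median SE of the 335 genes went from 0.11 to 0.099 and 0.085, and why calls were lost was not tested. As a part of the cause, thalamic tissue may be present: in Dp16 14 and 5xFAD-Dp16 1 the same genes were lower than in the other 3 libraries of their group by a mean of -0.14 (-0.16 and -0.12; one-sided exact p = 0.0625, the smallest the 16 choices allow), so that this part and the genotype, which stays open as untested, cannot be told apart, and the 1 5xFAD library of low thalamus score stood at -0.24 against WT.

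Plaque-associated microglia genes rose less with the transgenes on the Dp16 background (interaction median -0.33, a preset call that an estimated correlation does not keep). Thalamus and choroid plexus scores as covariates left -0.30 (quartiles -0.52 and -0.12), which argues against thalamic tissue as the whole cause. As most 5xFAD libraries were high in thalamus markers, this fit cannot fully separate tissue from genotype. Lower transgene expression cannot be told apart from equal expression, since Thy1, tested first without regard to neuron content, stood at 0.33 ± 0.15 in 5xFAD-Dp16 over 5xFAD (adjusted p = 0.26) but at -0.18 (error 0.13, exact p = 0.257) relative to the excitatory neuron score. That score was low in the 5xFAD libraries of high thalamus markers, which may itself move this value down. Thy1 counts also hold those of the mouse gene itself. Fewer microglia cannot be told apart from a weaker response per cell: the homeostatic score differed by -0.24, the plaque-associated score by -0.41, and the difference of both had an exact permutation p of 0.0857. An effect of the duplication itself stays open, and since the difference missed its exact test so does chance.

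Reads of agouti (a) marked carriers of the duplication, with 342 counts in the 8 carriers and 4 in the 8 others, 26 or more in every carrier and 2 at most in the others. Among the 33 genes within 1 Mb the highest log2 value in Dp16 against WT was 0.67, and none of them was called in either comparison by edgeR. This does not decide on spill from neighbours. A small share of a neighbour's reads could be counted to a without a visible change of that neighbour. Skin is argued against, since Krt5 and Krt14 together had an excess of 11 counts (176 against 165, counting error 18.5) and Krt14 had 5 against 18. A sequence carried together with the duplication is consistent with the split by carrier (Fisher's exact two-sided p = 0.000155), and agouti transgenes serve as coat-colour marks in chromosome-engineering vectors. Breeding from another strain stays open, as the labels do not give it, and this is a hypothesis found and tested on the same data.

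Against other splits of the same libraries, the real grouping alone reached its count of genes in several comparisons. These were Dp16 against WT (39, highest other 1), 5xFAD against WT (1244, highest other 0) and 5xFAD-Dp16 against Dp16 (518, highest other 0). The same held for 5xFAD-Dp16 against WT (548, highest other 0) and female against male (11, highest other 1). This is 1 of 35 splits, or 1 of 60 between the sexes, the smallest share such splits can give. It was not adjusted over the 8 comparisons, and sets that mix genotypes carry the genotype effect in their spread. Chance is thus made less likely for these counts but is not excluded. For 5xFAD-Dp16 against 5xFAD, 3 of 35 splits, the real one among them, gave at least the real count (52, highest other 1880). The count alone thus leaves chance open. Of the 52 genes, 32 lay in the segment and all rose, with 96 of its 105 genes positive. Segment means per library differed by 0.47 (exact permutation p = 0.0286, the smallest possible), which argues against chance for the segment. For the 20 genes outside it chance stays open. For the interaction and the sex difference of the 5xFAD effect the real count was 0, which all 60 of 60 splits reach by construction, so these splits decide nothing (highest others 1588 and 1). The split with 1880 set 5xFAD-Dp16 1 and 5xFAD 6, 13 and 15, all high in thalamus markers, against the rest, and it points to a structure of the samples beyond the genotypes. For the number of lists past the preset correlation chance cannot be excluded by these splits, of which 16 of the 35 set 3 libraries of a genotype against 1 and so keep part of its effect: in the order of the 8 comparisons the real counts were 8, 21, 19, 15, 15, 14, 14 and 14, the highest others 17, 23, 19, 24, 25, 22, 20 and 23, and the splits as large 31 of 35, 5 of 35, 2 of 35, 14 of 35, 19 of 35, 20 of 60, 17 of 60 and 23 of 60. In the 18 splits of the first 5 comparisons with 2 libraries of each genotype on both sides, the highest count of genes was 0 in each, the median count of lists was 11.5, 8, 10.5, 10.5 and 9, the highest 17, 15, 16, 15 and 18, and the splits as large as the real one 15, 0, 0, 1 and 3.

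Single libraries stood far from the other 3 of their group in 18 of 184 sets of 4 values, where chance gives about 1 in 20. The sets are measures of the same 16 libraries and are not independent, so that the 2 rates cannot be compared by a test. Thalamus scores set apart WT 4 (1.3), Dp16 14 (1.65), 5xFAD 10 (-0.51) and 5xFAD-Dp16 1 (1.16). Excitatory neuron scores set apart WT 4 (-0.34) and Dp16 14 (-0.40), and synaptic protein scores Dp16 14 (-0.16) and 5xFAD-Dp16 9 (0.099). Further scores of 5xFAD-Dp16 1 stood apart for dentate gyrus (-0.66), mural cells (0.65), immediate early genes (0.033) and chromosome 21 orthologs on chromosomes 10 and 17 (0.17). The interferon response of Dp16 12 was 0.47 (others -0.035 to 0.032), the endothelial score of WT 7 0.19, the choroid plexus score of Dp16 5 -1.29 (others -3.96 to -3.50), the cholesterol score of 5xFAD 10 0.35, and the oxidative phosphorylation score of Dp16 14 0.13. Sod1 was at 195 CPM in WT 2 (others 220 to 224).

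The effect of the transgenes differed between the backgrounds, by the preset test of the interaction, in 14 lists, all lost with an estimated correlation. Their medians were -0.33 for plaque-associated microglia, -0.11 for complement, -0.17 for interferon response, -0.26 for antigen presentation, -0.14 for reactive astrocytes, -0.086 for lysosome, 0.30 for excitatory neurons, 0.41 for CA1 and CA3, 2.27 for choroid plexus, -0.76 for thalamus, 0.43 for immediate early genes, 0.21 for synaptic proteins, -0.28 for oxidative phosphorylation and 0.27 for protocadherins. Between the sexes, female minus male, it differed in 14 lists by the same test, again all lost with an estimated correlation. High thalamus markers were uneven between the compared sets, so that tissue content cannot be fully told apart from sex. These medians were 0.28 for plaque-associated microglia, 0.30 for complement, 0.13 for lysosome, -0.41 for excitatory neurons, -0.19 for dentate gyrus, -0.35 for CA1 and CA3, 0.13 for astrocytes, 0.28 for mature oligodendrocytes, 0.57 for meningeal fibroblasts, 2.11 for thalamus, 1.01 for blood cells, 0.97 for lymphocytes and neutrophils, -0.22 for synaptic proteins and -0.18 for protocadherins.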

How the results depend on the processing

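The covariates, the removal of the length trend and the omission of the 6 libraries of high thalamus markers were chosen only after the data were seen. Of 151 calls of named genes, 95 of the 146 that could be tested were lost in males alone, 53 of 146 in females alone, 40 of 146 without the 6 libraries, 34 of 144 with the compared groups alone, and 33 of the 151 in at least 1 of the runs without a single library. The length trend lost 19, the scores as covariates 12, the block 11, each RPKM scale 10, DESeq2's size factors 4, no filter 3, limma-voom, TMM factors from outside the segment and no sex term 2 each, the CPM filter 1 and DESeq2 0 of 148. None of these 151 calls changed direction in any alternative run in which its gene could be tested, and the segment kept its direction under all. Other called genes named here were not followed in these runs. With each library left out in turn the counts ranged from 28 to 37 in Dp16 against WT, 562 to 3486 in 5xFAD against WT, 32 to 2045 in 5xFAD-Dp16 against 5xFAD, 384 to 528 against Dp16, 435 to 491 against WT and 8 to 11 between the sexes, and were 0 throughout for the interaction and the sex difference of the 5xFAD effect. Depth limits the ratios of genes with 1 to 3 counts in a group, such as the interval of 26.6 to 5960 for agouti. Without a filter on low counts the 8 comparisons, in the order given, called 360, 2692, 1656, 890, 942, 290, 330 and 283 genes, and the cause was not tested. With fewer samples, the compared groups alone gave 516 in 5xFAD against WT and 10 in 5xFAD-Dp16 against 5xFAD; females alone gave 0 in Dp16 against WT, 5 against 5xFAD and 261 against WT; males alone gave 0 in Dp16 against WT, 76 in 5xFAD against WT, 0 in 5xFAD-Dp16 against 5xFAD, 54 against Dp16 and 51 against WT. The sample number as a block gave 7 between the sexes. DESeq2 called 72, 2115 and 708 in the first 3 comparisons, 1 for the interaction and 29 between the sexes; the cause was not tested. On the log2 of RPKM plus 1 the medians of the segment were 0.39 and 0.29, since the added 1 shrinks the folds of genes of low RPKM. Among genes called in either comparison, chosen for their change, the correlations across genes were 0.893 for the 5xFAD and 0.963 for the Dp16 effect.

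Without the 6 libraries of high thalamus markers, which leaves 1 5xFAD library assumed to vary like the rest, the counts were 69 in Dp16 against WT, 301 in 5xFAD against WT, 101 in 5xFAD-Dp16 against 5xFAD and 15 for the interaction, and the median of the segment against 5xFAD was 0.63. The tests of lists changed direction there in 5xFAD against WT (mature oligodendrocytes -0.34, oxidative phosphorylation -0.013), against 5xFAD (inhibitory neurons -0.033, mature oligodendrocytes 0.53, immediate early genes -0.12, synaptic proteins -0.0071) and in the interaction (excitatory neurons -0.045, thalamus 0.16, immediate early genes 0.014, synaptic proteins -0.14); the cause was not tested. With the scores as covariates, which by construction take out the choroid plexus and thalamus lists, tests of lists changed direction in Dp16 against WT (choroid plexus -0.031), against 5xFAD (mature oligodendrocytes -0.043), in the interaction (choroid plexus -0.18) and in the sex difference (excitatory neurons 0.26, dentate gyrus 0.11, CA1 and CA3 0.12, mature oligodendrocytes -0.13, meningeal fibroblasts -0.19, thalamus 0.014, synaptic proteins 0.15, protocadherins 0.011). With the length trend removed oxidative phosphorylation in 5xFAD against WT was -0.041, and without single libraries mature oligodendrocytes against 5xFAD ranged from -0.52 to 0.0063. With an estimated correlation 28 of 120 list calls held, among them each of plaque-associated and homeostatic microglia, complement, interferon response, antigen presentation, reactive astrocytes, lysosome and Alzheimer risk orthologs in the 3 comparisons of the transgenes with mice lacking them.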

Other observations

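The genes described here were chosen only after their values were seen. Of the genes of the triplicated segment, 4 rose with the transgenes on both backgrounds. Mx1 and Mx2, annotated as polymorphic pseudogenes, rose in 5xFAD against WT (2.75 and 2.30, adjusted p = 0.00577 and 0.0218) and in 5xFAD-Dp16 against Dp16 (2.48 and 1.94, adjusted p = 0.00753 and 0.0432). Runx1, a transcription factor of blood and microglia, rose by 1.54 and 1.83, and the signalling adaptor gene Samsn1 by 2.21 and 2.37. Ifnar2 rose in 5xFAD against WT (0.53, adjusted p = 0.00595), and the receptor cluster had 0 of 4 genes called by edgeR in 5xFAD-Dp16 against Dp16 (2 when adjusted over the list alone). In 5xFAD against WT 7 genes of the segment were called higher and 4 lower. Among those that fell were the synaptic phosphatase gene Synj1 (-0.50, adjusted p = 0.0241) and the corepressor gene Nrip1 (-0.62, adjusted p = 0.0237). Whether these calls hold without single libraries was not examined.

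C4b, which rose with the transgenes on both backgrounds, stood at 66.9 ± 4.83 CPM (SD) in WT, 98.3 ± 28.5 in Dp16, 287 ± 64 in 5xFAD and 363 ± 26.8 in 5xFAD-Dp16, each over 4 libraries. It was not called in Dp16 against WT (adjusted p = 0.371) or in 5xFAD-Dp16 against 5xFAD (adjusted p = 0.187). Inhba, which fell with the transgenes on the WT background, stood at 5.85 ± 0.41 CPM in Dp16 and 5.18 ± 1.24 in 5xFAD-Dp16, and the difference between the backgrounds was not called. Tbx1 was low in both groups with the duplication, at 0.4 ± 0.221 and 0.442 ± 0.116 CPM, against 1.63 ± 0.501 in WT and 1.73 ± 0.397 in 5xFAD.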
